A study of Mus musculus with 6 samples.

How the data were processed

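RNA from 6 libraries of lung innate lymphoid cells (ILCs) was analysed, 3 from KLRG1-negative and 3 from KLRG1-positive cells; the labels' protocols call the second sort KLRG1-high. The mice were wild-type C57BL/6 animals carrying a green fluorescent protein reporter at the Il4 gene (4get). They received 500 ng of interleukin-33 by intraperitoneal injection for 4 days and were killed on day 5, per the labels. Per the labels' protocols, cells without lineage markers and with CD90 were sorted to a stated purity above 90%, cDNA was made and amplified with a SMARTer low-input kit, and libraries were built with Nextera XT, a method that does not mark strand. The lineage panel is not given in the sources used here. The labels do not say whether the 3 samples of a group came from separate mice, so p-values measure only the spread between these samples, which may be technical.

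The deposited table holds raw counts of reads per gene made by the authors with featureCounts, without normalization, per the file headers. Per the file headers, reads were counted on Ensembl release 90 gene models of mouse genome build GRCm38, as reads rather than read pairs, without strand, and with multi-mapping and ambiguous reads left out. The submitters' processing notes also name bcl2fastq, STAR 2.4.1d and Subread 1.5.2. Gene length is given in the deposited table as another column and entered no test. The table lists 52636 genes, of which 26868 had at least 1 count. Symbols and gene classes came from GENCODE release M21, the same genome build, in which 52489 identifiers were found and 95.2% of those had the same start and end. Coordinates are those of the deposited table.

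Assigned counts ranged from 17323004 to 23946073 per library. Multi-mapping alignments made up 26.3 to 32.3% of each library, and alignments outside gene models 4.76 to 10.4%. Because multi-mapping reads were left out, genes with close copies or processed pseudogenes are understated: Gapdh averaged only 14.1 CPM (counts scaled to a common library total) in KLRG1-negative and 22.7 CPM in KLRG1-positive cells, and protein-coding ribosomal protein genes made up 0.374 to 0.457% of counts. Values of paralogs (haemoglobin, Hspa1a and Hspa1b, H2 and Klr genes, T cell receptor and immunoglobulin segments) and of overlapping or antisense genes are therefore uncertain. A sum of 3 counts over a group, the floor used here for a count of 0, corresponded to 0.0508 CPM in the KLRG1-positive and 0.0468 CPM in the KLRG1-negative libraries. Counting intervals (95%, exact conditional binomial) and floors cover counting error only, since amplified reads are not independent molecules.

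Computation started from the deposited counts. Differences were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test with robust dispersion, TMM factors and the filterByExpr filter by group, which kept 15197 genes. P-values were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05; an adjusted p given without another name comes from this test. Standard errors are those of the log2 fold change, derived from the F statistic. CPM values were divided by the TMM-scaled library size, and positive log2 fold changes mean higher levels in KLRG1-positive cells. The median log2 fold change over all tested genes was -0.05 with TMM, -0.05 with DESeq2 size factors and -0.08 with library size only. The biological coefficient of variation was 0.631.

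The 20 gene lists, the tests, the rule for named genes and the alternative settings were fixed before the data were examined. Lists were tested against all other tested genes with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 20 lists. With the correlation estimated per list, 0 lists passed, and fry, which tests whether a list's genes move on balance 1 way and compares them with no other genes, called 3. Named genes were of 3 kinds. The first were the 10 protein-coding genes with the largest positive and the 10 with the largest negative log2 fold change among those past the threshold, with non-overlapping groups and a mean of at least 10 CPM in the higher group. The second were 14 fixed genes, among them Klrg1, Thy1, Il4, Gata3, Rora, Il1rl1, Il7r, Il5, Il13, Areg, Arg1, Tbx21 and Tcf7. The third were up to 2 higher and 2 lower members per list, or the 2 most abundant where none passed. Some results under this rule are not reported. Any gene outside this rule was chosen after its values were seen.

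Replicate numbers from the labels were checked for pairing. Across genes, which are not independent replicates, the deviations of same-numbered libraries from their group means correlated at 0.38, 0.34 and 0.19 for numbers 1, 2 and 3, and all 6 libraries correlated best with the library of their own number. With 3 libraries per group these 6 agreements are not independent of each other. The numbers were read as pairing the samples, a reading that comes from the data and not from the labels. The main test, fixed before the data were examined, holds the group only and ignores this pairing. Only the fits with the replicate number as a block take it into account.

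Alternatives were DESeq2 size factors, upper-quartile factors or library size in place of TMM, no filter or a stricter filter (10 counts in all 3 libraries of a group), DESeq2 1.42.0, limma-voom, the replicate number as a block, a minimum absolute log2 fold change of 1, and leaving out each library. Leaving out both libraries of a number, and DESeq2 with the block, were added after seeing the data. The procedure was tested on simulated counts for this comparison with 14557 genes fitted and 50 genes changed at each fold size. The quasi-likelihood test recovered 2% of genes changed 2-fold, 22% at 4-fold, 84% at 16-fold and 96% at 64-fold, and DESeq2 recovered 18%, 66%, 96% and 98%. Of the unchanged genes, the quasi-likelihood test called 6 and DESeq2 92, and with no change simulated they called 0 and 62.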

Results

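Gene expression was measured by RNA sequencing in 2 populations of innate lymphoid cells (ILCs) sorted from mouse lung after interleukin-33 treatment. ILCs are lymphocytes without rearranged antigen receptors, and interleukin-33 is an alarmin that activates the group 2 subset (ILC2), which makes type 2 cytokines. The populations differed in KLRG1, a lectin-like receptor found on activated ILC2 and on some NK and T cells. Each population had 3 libraries. The KLRG1-negative libraries held 17898268, 23946073 and 21723304 assigned counts, and the KLRG1-positive libraries 17323004, 19042555 and 23421426. The design asks how the transcriptomes of the 2 populations differ.

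Klrg1 itself, which separated the sorts and so checks the labels, stood at 13.1, 193 and 73.2 CPM in the KLRG1-negative libraries and at 1485, 1786 and 1327 CPM in the KLRG1-positive ones (ENSMUSG00000030114, GRCm38 chromosome 6, 122270596 to 122282882, minus strand). Its log2 fold change was 4.04 ± 0.93 (SE, n = 3 per group) with an edgeR quasi-likelihood adjusted p of 0.0939, above the threshold, and the KLRG1-negative libraries differed widely from each other. Thy1, which encodes the CD90 used in the gate, stood at 53.1, 44.8 and 25.9 CPM in the KLRG1-negative and at 34.9, 16.3 and 24.4 CPM in the KLRG1-positive libraries, a difference that did not pass (adjusted p = 0.491). Every KLRG1-positive library lay above every KLRG1-negative library in Gata3 and Rora, transcription factors of ILC2. Gata3 averaged 967 ± 146 against 355 ± 181 CPM (log2 fold change 1.45 ± 0.42 SE, adjusted p = 0.156), and Rora 713 ± 221 against 351 ± 183 CPM (1.02 ± 0.44, adjusted p = 0.34). Neither gene passed the test.

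**Figure D1:**
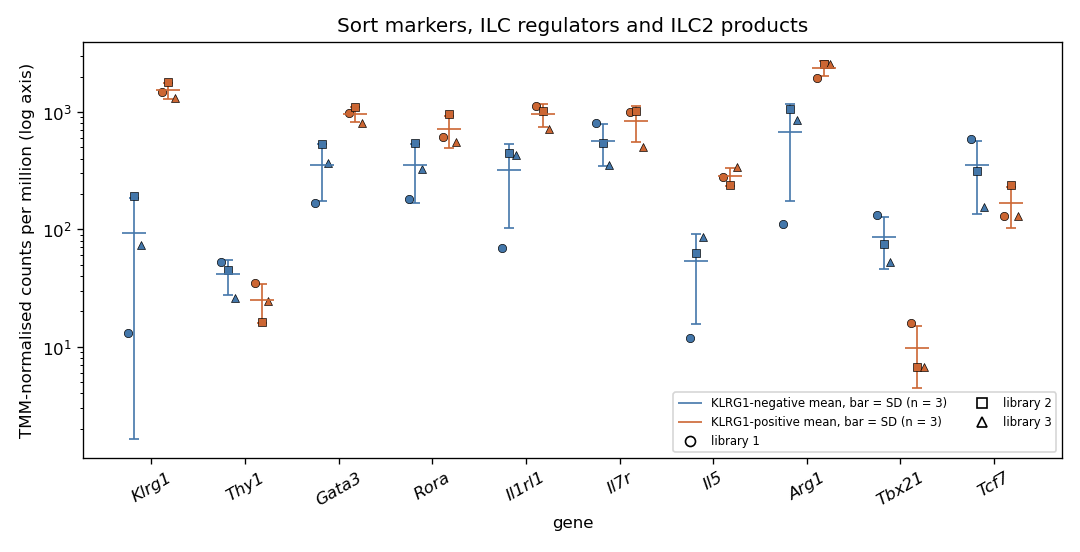
Levels of 10 genes in each library, as TMM-normalised CPM on a log axis. Points are libraries, horizontal marks are means and bars are SDs (n = 3 per group); Klrg1 lay at 1327 CPM or above in each KLRG1-positive library and at 193 CPM or below in each KLRG1-negative library.

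The KLRG1-positive libraries had higher levels of the chemokine receptors Ccr1 and Ccr2, of the leukotriene-synthesis enzyme Alox5 and of the integrin chain Itgb7. They had lower levels of the lymph node homing receptor Ccr7, of the costimulatory receptor Cd28, and of several genes for extracellular matrix proteins. The KLRG1-negative libraries also held T cell, B cell and fibroblast transcripts, with Cd3e at 395, Ighm at 13659 and Col3a1 at 3586 CPM on average. Whether the lower genes differed within ILCs therefore cannot be told. A lower share of ILCs in those libraries would also make ILC genes higher in KLRG1-positive cells. Ccr2 and Itgb7 differed 3.67- and 2.09-fold, Ccr1 and Alox5 4.29- and 6.81-fold, against 2.73-fold for Gata3 and 3.49-fold for Arg1. How far the higher genes differed within ILCs therefore cannot be told either. In all, 19 genes were higher and 184 lower in KLRG1-positive cells among 15197 tested. At an unadjusted p under 0.05 the numbers were 637 and 1752. Of the genes tested, 24.6% had non-overlapping groups, against 10% by chance. The counts depended on single libraries: without KLRG1-negative library 1, 2 or 3 the test called 3, 0 and 0 genes higher and 91, 4 and 0 lower, and without KLRG1-positive library 1, 2 or 3 it called 5, 0 and 0 higher and 159, 0 and 1 lower (edgeR quasi-likelihood; in all fits with libraries left out, 406 to 1048 genes were higher and 1159 to 1779 lower at an unadjusted p under 0.05, and DESeq2 called 112 to 551 higher and 864 to 1555 lower). With the replicate number as a block it called 0 genes higher and 53 lower, 34 of them among the 184 (1025 and 1876 at an unadjusted p under 0.05), while DESeq2 with the same block, a fit added after seeing the data, called 609 and 1697. Leaving out both libraries numbered 1, 2 or 3, also added, gave 3, 0 and 0 genes higher and 168, 0 and 0 lower.

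Among the 10 genes with the largest increases, Alox5, which encodes 5-lipoxygenase, averaged 574 ± 164 CPM in KLRG1-positive and 84.3 ± 36.0 CPM in KLRG1-negative cells (SD, n = 3; log2 fold change 2.77 ± 0.40 SE, adjusted p = 0.043; chromosome 6, 116410077 to 116461178). Ccr2, the receptor for the chemokine CCL2, averaged 1132 ± 192 against 309 ± 54.3 CPM (1.87 ± 0.21, adjusted p = 0.0272; chromosome 9, 124101950 to 124113557). Ccr1 averaged 57.3 ± 5.70 against 13.4 ± 3.79 CPM (2.10 ± 0.29, adjusted p = 0.041). The zinc transporter Slc39a4 averaged 118 ± 2.37 against 31.9 ± 6.80 CPM (1.89 ± 0.22, adjusted p = 0.0293), and the riboflavin transporter Slc52a3 94.3 ± 11.1 against 25.7 ± 1.62 CPM (1.88 ± 0.20, adjusted p = 0.0227). Trp73, a p53 family gene, was nearly undetected in KLRG1-negative cells (0.0452 ± 0.0483 CPM) and reached 4.11, 11.2 and 20.3 CPM in the KLRG1-positive libraries (log2 fold change 7.83, adjusted p = 0.043). The KLRG1-negative libraries held 3 Trp73 counts, a ratio to the KLRG1-positive level of 0.00373 with a counting interval of 0.000767 to 0.0109. Tiam2, Rps6ka5, Sytl2 and Osbpl3 completed the 10, with log2 fold changes of 3.73, 1.57, 1.40 and 1.37. With the block, the adjusted p of these 10 genes lay between 0.0549 and 0.101, so none of the 10 passed in that fit, and all 10 kept their direction.

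The 10 genes with the largest decreases had few or no counts in KLRG1-positive cells. Since fibroblast transcripts were abundant in the KLRG1-negative libraries, whether these genes differed within ILCs cannot be told. Lum, which encodes the matrix proteoglycan lumican, averaged 143 ± 81.5 CPM in KLRG1-negative cells (SD, n = 3) and had 1 count over the 3 KLRG1-positive libraries, a ratio of 8233 with a counting interval of 1477 to 325223 (adjusted p = 0.0124). Col6a5, a collagen VI chain, averaged 214 ± 141 CPM against 2 counts, a ratio of 6512 with a counting interval of 1802 to 53776 (adjusted p = 0.0174). Against the floor of 3 counts over the group, Aldh1a3, a retinaldehyde dehydrogenase, was at least 887-fold lower in KLRG1-positive cells, the G protein-coupled receptor gene Mrgprg at least 726-fold, Lrrc17 at least 530-fold and the growth factor receptor Egfr at least 481-fold. Mrgprg was even across the KLRG1-negative libraries, at 34.1, 35.7 and 40.9 CPM. Zfp185, Nnmt, Col6a6 and Adamts15 were at least 412-, 411-, 384- and 318-fold lower by the same floor. Of the 184 lower genes, 103 stayed under 1 CPM in every KLRG1-positive library and 27 had no count there. With the block, Lum and Col6a5 still passed (adjusted p = 0.0409 for each) and the other 8 did not, with adjusted p up to 0.109.

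**Figure D2:**
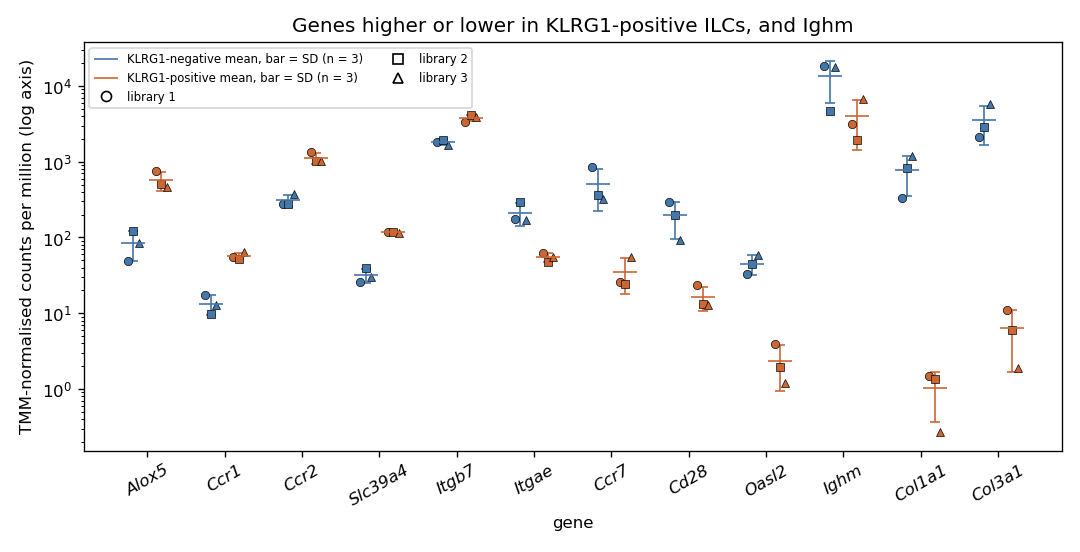
Levels of 12 genes in each library, as TMM-normalised CPM on a log axis. Points are libraries, horizontal marks are means and bars are SDs (n = 3 per group); all genes shown except Ighm passed the quasi-likelihood test, with Col3a1 averaging 3586 CPM in KLRG1-negative and 6.31 CPM in KLRG1-positive cells.

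Genes that mark ILC2 stood higher as a group in KLRG1-positive cells. All 14 tested members of the list of ILC2 identity genes and receptors had positive log2 fold changes, with a median of 1.23, but 0 passed over all genes and 0 when adjusted over the list alone (edgeR quasi-likelihood; 5 had an unadjusted p under 0.05). As a set the list passed camera (adjusted p = 2.92e-05), and did not with an estimated correlation (adjusted p = 0.364 with an estimated correlation). Its most abundant members were Arg1, the enzyme arginase 1, at 2361 ± 345 against 676 ± 502 CPM (1.80 ± 0.75 SE, adjusted p = 0.32), and Il7r, the interleukin-7 receptor chain, at 841 ± 289 against 570 ± 224 CPM (0.56 ± 0.39, adjusted p = 0.598). Il1rl1, which encodes the interleukin-33 receptor ST2, averaged 958 ± 210 against 318 ± 215 CPM (1.59 ± 0.67, adjusted p = 0.324). KLRG1-negative library 1 lay apart in part of the list. The KLRG1-negative libraries held 110, 1069 and 847 CPM of Arg1 and 69.8, 451 and 434 CPM of Il1rl1. In Il7r library 1 was instead the highest of them (803, 549 and 357 CPM). Without library 1 the set still passed camera (adjusted p = 0.000495). Of the 14 tested type 2 cytokines and ILC2 mediators, 11 had positive log2 fold changes, with a median of 1.79; 0 passed over all genes and 1, Il4, when adjusted over the list alone (edgeR quasi-likelihood; 3 were higher at an unadjusted p under 0.05, and DESeq2 gave an adjusted p of 0.00401 for Il5). The set passed camera (adjusted p = 0.00013; adjusted p = 0.364 with an estimated correlation). KLRG1-negative library 1 lay apart in much of this list too. The KLRG1-negative libraries held 11.8, 63.2 and 86.6 CPM of Il5 and 1.78, 38.9 and 22.3 CPM of Il6. In Il4 they differed less (1.39, 2.17 and 1.49 CPM), and in Il10 library 3 was the lowest of them. Without KLRG1-negative library 1 this set still passed camera (adjusted p = 0.00239). Il5 averaged 285 ± 50.9 against 53.9 ± 38.2 CPM (a 5.29-fold difference, adjusted p = 0.153), Areg 121 ± 90.3 against 20.2 ± 21.7 CPM (2.58 ± 1.38, adjusted p = 0.458), Il4 8.31 ± 1.64 against 1.68 ± 0.423 CPM (2.30 ± 0.49, adjusted p = 0.0786) and Il13 7.85 ± 2.89 against 2.61 ± 2.22 CPM (1.58 ± 0.99, adjusted p = 0.54). In the same libraries the T cell gene Cd3e stood at 20.1 ± 16.5 CPM in KLRG1-positive and 395 ± 352 CPM in KLRG1-negative cells (adjusted p = 0.0813, and 0.0468 with the block, in which it passed). The B cell list was lower as a set in KLRG1-positive cells by camera (adjusted p = 2.74e-05), but not with an estimated correlation (adjusted p = 0.364). A lower share of ILC2 in the KLRG1-negative libraries would also place the ILC2 and cytokine sets higher in KLRG1-positive cells. Whether these sets differed within ILC2 therefore cannot be told.

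Proliferation and glycolysis genes also stood higher as sets. All 32 cell cycle genes had positive log2 fold changes (median 1.15), and 0 passed over all genes or adjusted over the list alone (5 had an unadjusted p under 0.05 by edgeR quasi-likelihood). The set passed camera (adjusted p = 7.68e-06; adjusted p = 0.453 with an estimated correlation). The replication helicase genes Mcm6 and Mcm3 averaged 782 ± 301 against 517 ± 116 CPM and 525 ± 255 against 230 ± 59.5 CPM. KLRG1-positive library 2 lay apart, with 231 CPM of Mcm3 against 650 and 692, within the KLRG1-negative range of 162 to 270 CPM. Every KLRG1-positive library lay above every KLRG1-negative library for only 1 of the 32 genes, against 9.46% of all tested genes. All 15 tested glycolysis genes had positive log2 fold changes (median 0.68); 0 passed over all genes and 3 were higher when adjusted over the list alone (7 at an unadjusted p under 0.05 by edgeR quasi-likelihood). The set passed camera (adjusted p = 8.8e-06; adjusted p = 0.364 with an estimated correlation). Ldha, lactate dehydrogenase A, averaged 1671 ± 211 against 836 ± 57.5 CPM (1.00 ± 0.17, adjusted p = 0.0541), and Pkm, pyruvate kinase, 723 ± 225 against 418 ± 43.3 CPM (0.79 ± 0.25, adjusted p = 0.194). In the same libraries Cd3e averaged 20.1 against 395 CPM, without passing in the main test (adjusted p = 0.0813, and 0.0468 with the block, in which it passed). Since the KLRG1-negative libraries held more transcripts of other cells, whether proliferation or glycolysis genes differed within ILCs cannot be told.

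Markers of other ILC subsets were lower as sets in KLRG1-positive cells. Of 19 tested ILC1 and NK cell markers, 17 had negative log2 fold changes (median -2.35); 0 passed over all genes (edgeR quasi-likelihood; 9 were lower at an unadjusted p under 0.05) and 5 were lower when adjusted over the list alone. The set passed camera (adjusted p = 8.8e-06; adjusted p = 0.364 with an estimated correlation). Tbx21, the T-box factor of ILC1, NK and some T cells, averaged 9.77 ± 5.29 against 86.2 ± 40.6 CPM (log2 fold change -3.14 ± 0.54 SE, adjusted p = 0.0561, and 0.0425 with the block, in which it passed). Nkg7, a cytotoxic granule gene, averaged 143 ± 98.4 against 726 ± 402 CPM (-2.35 ± 0.63, adjusted p = 0.13), and Il2rb 355 ± 53.8 against 558 ± 225 CPM (adjusted p = 0.393). Of 13 tested ILC3 markers, 9 had negative log2 fold changes (median -0.91), 0 passed over all genes (edgeR quasi-likelihood; 6 were lower and 1 higher at an unadjusted p under 0.05) and 5 were lower when adjusted over the list alone. That set passed camera narrowly (adjusted p = 0.0461; adjusted p = 0.364 with an estimated correlation), and missed the threshold with the block (0.074) and without KLRG1-negative library 2 (0.0806), KLRG1-positive library 1 (0.0996) or KLRG1-positive library 3 (0.0721), and without both libraries numbered 1, 2 or 3 (0.089, 0.0517 and 0.0681). With the block 1 member, Il23r, passed (adjusted p = 0.0494). The list's most abundant members leaned the other way, with Ltb at 970 ± 275 against 795 ± 173 CPM and Kit at 324 ± 56.7 against 180 ± 69.8 CPM. Several genes on both lists are also expressed by T or B cells, whose markers moved the same way.

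T and B cell markers were lower as sets in KLRG1-positive cells. Of 18 tested T cell markers, 16 had negative log2 fold changes (median -3.37). Cd28 was the 1 member that passed over all genes, at 16.5 ± 5.87 against 196 ± 102 CPM (-3.57 ± 0.51 SE, adjusted p = 0.043, and 0.0526 with the block, in which it did not pass). With the block 4 other T cell markers passed instead, Trac (adjusted p = 0.0409), Cd3e (0.0468), Cd3d (0.0494) and Themis (0.0494). Adjusted over the list alone, 11 were lower and 1, Tcrg-C4, higher. The set passed camera (adjusted p = 8.8e-06; adjusted p = 0.364 with an estimated correlation). All 10 B cell markers had negative log2 fold changes (median -3.42), with 0 passing over all genes (edgeR quasi-likelihood) and all 10 lower when adjusted over the list alone, as at an unadjusted p under 0.05; with the block 4 passed, among them Cd79a, Ms4a1 and Ebf1 (adjusted p = 0.0409, 0.0409 and 0.0494). As a set, B cell markers passed camera (adjusted p = 2.74e-05; adjusted p = 0.364 with an estimated correlation). The immunoglobulin heavy chain gene Ighm averaged 3989 ± 2543 against 13659 ± 7760 CPM (-1.78 ± 0.67, adjusted p = 0.271). It was the most abundant gene in KLRG1-negative libraries 1 and 3, with 1.84% and 1.72% of all counts. The light chain gene Igkc averaged 851 ± 461 against 5531 ± 3232 CPM (adjusted p = 0.112).

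The mixed list of epithelial, endothelial and stromal markers was lower as a set in KLRG1-positive cells, and its members that passed were fibroblast genes. Of 14 tested epithelial, endothelial and stromal markers, 4 were lower in KLRG1-positive cells, 0 were higher and 10 did not pass; adjusted over the list alone, 6 were lower. The 4 were Col1a1, Col1a2, Col3a1 and Dcn, which encode fibrillar collagens and decorin and are made by fibroblasts. Col3a1 averaged 6.31 ± 4.62 against 3586 ± 1918 CPM (-9.15 ± 0.94 SE, adjusted p = 0.0217; chromosome 1, 45311538 to 45349706), and Col1a1 1.02 ± 0.657 against 778 ± 424 CPM (-9.59 ± 0.93, adjusted p = 0.0217; chromosome 11, 94936224 to 94953042). With the block the adjusted p values were 0.0686 and 0.068, and none of the 4 passed. The list's median log2 fold change was -2.22 and it passed camera (adjusted p = 4.19e-06; adjusted p = 0.364 with an estimated correlation). The surfactant gene Sftpc on this list did not follow the sort: it stood at 366 and 330 CPM in the libraries numbered 1 of the 2 populations and at or below 2.33 CPM in the other 4.

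Trafficking genes changed in both directions. Of 16 tested trafficking and residency genes, 2 were higher (Ccr2 and Itgb7), 3 were lower, among them Ccr7 and Itgae, and 11 did not pass; adjusted over the list alone, 4 were higher and 4 lower. Itgb7 averaged 3783 ± 375 against 1812 ± 156 CPM (1.06 ± 0.16 SE, adjusted p = 0.0462; chromosome 15, 102215995 to 102231935). Ccr7 averaged 35.3 ± 17.5 against 510 ± 286 CPM (-3.85 ± 0.55, adjusted p = 0.043), and Itgae, an integrin chain of tissue-resident lymphocytes, 54.9 ± 7.34 against 213 ± 69.9 CPM (-1.96 ± 0.28, adjusted p = 0.043). With the block none of the 5 passed, with adjusted p of 0.068 for Ccr2, 0.0686 for Itgb7, 0.0913 for Ccr7 and 0.0945 for Itgae. The list did not pass camera (adjusted p = 0.591), and its median (0.17) and mean (-0.37) differed in sign. Ccr7 is also expressed by naive T and B cells, whose marker lists were lower in KLRG1-positive cells.

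Interferon response genes were lower as a set in KLRG1-positive cells. Of 16 tested, 15 had negative log2 fold changes (median -1.10), and 1, the antiviral gene Oasl2, passed over all genes at 2.35 ± 1.42 against 45.3 ± 13.4 CPM (-4.27 ± 0.57 SE, adjusted p = 0.038, and 0.0898 with the block, in which it did not pass). Adjusted over the list alone, 9 were lower. The set passed camera (adjusted p = 8.8e-06; adjusted p = 0.364 with an estimated correlation), and fry also called it (adjusted p = 0.0361), as it did the ILC3 list and the mixed list with stromal markers. By camera the B cell list was also lower as a set in KLRG1-positive cells, but it did not pass with an estimated correlation (adjusted p = 0.364) or by fry (adjusted p = 0.107).

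**Figure D3:**
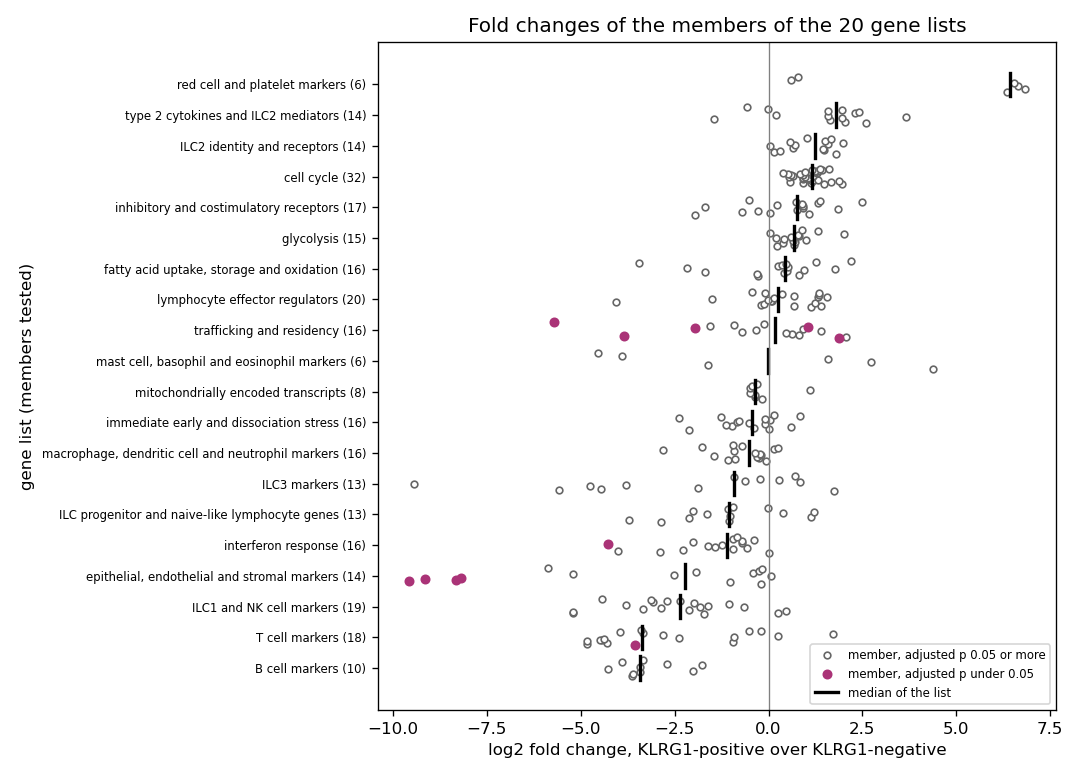
Log2 fold changes of the tested members of each of the 20 gene lists, KLRG1-positive over KLRG1-negative. Open points are members with an adjusted p of 0.05 or more, filled points members under it, and black bars list medians, which ran from -3.42 for B cell markers to 6.45 for red cell and platelet markers.

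The other 9 lists did not pass camera, and of their members none passed over all genes (edgeR quasi-likelihood). The progenitor and naive-like list had a median of -1.05 (camera adjusted p = 0.0725, 0.0309 without KLRG1-negative library 3, 0.0471 without both libraries numbered 3 and 0.0426 without the filter); adjusted over the list alone, 3 members were lower and 1 higher, and 5 and 1 had an unadjusted p under 0.05. Its most abundant members were Id2, at 1595 ± 39.4 against 730 ± 255 CPM, and Ly6a, at 411 ± 96.2 against 314 ± 114 CPM, and Tcf7 averaged 167 ± 63.9 against 352 ± 217 CPM. The lymphocyte effector regulators had a median of 0.25 (camera adjusted p = 0.0692, 0.0274 with the block, 0.0331 without KLRG1-negative library 3 0.0134 without KLRG1-positive library 1, 0.0268 without both libraries numbered 1 and 0.0426 without the filter), with 3 members higher and 1 lower when adjusted over the list alone. Its most abundant members differed little, with Junb at 1923 ± 1300 against 1724 ± 1271 CPM and Ets1 at 1552 ± 550 against 1779 ± 216 CPM. The inhibitory and costimulatory receptors had a median of 0.77 (camera adjusted p = 0.0835, and 0.0469 with the block) and 0 members past the threshold when adjusted over the list alone, with Pdcd1 at 439 ± 142 against 233 ± 159 CPM and Cd96 at 198 ± 51.7 against 241 ± 136 CPM. The fatty acid list had a median of 0.43 (camera adjusted p = 0.0779, and 0.0426 without the filter) and 0 such members, with Acaa2 at 186 ± 26.4 against 227 ± 30.5 CPM and Cpt1a at 227 ± 71.7 against 162 ± 42.6 CPM.

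Among the remaining lists, macrophage, dendritic cell and neutrophil markers had a median of -0.53 (camera adjusted p = 0.149), with Cd74 at 1591 ± 364 against 2941 ± 2767 CPM and H2-Ab1 at 641 ± 220 against 752 ± 708 CPM. The 6 tested mast cell, basophil and eosinophil markers had a median of -0.01 and a mean of -0.23, both opposite in sign to camera's direction (adjusted p = 0.591); adjusted over the list alone, 2 were higher and 1 lower. Among them were Cpa3 at 51.5 ± 34.0 against 7.82 ± 4.93 CPM (adjusted p = 0.13) and Ccr3 at 41.8 ± 7.45 against 2.02 ± 2.59 CPM (adjusted p = 0.175). Immediate early and dissociation stress genes had a median of -0.45 (camera adjusted p = 0.259, and 0.0181 without KLRG1-negative library 1). They differed more by library number than by sort: Fos stood at 81.8, 2166 and 2044 CPM in the KLRG1-negative and at 223, 2147 and 1623 CPM in the KLRG1-positive libraries, and Dusp1 at 68.4, 1886 and 1115 CPM and at 24.1, 2755 and 1903 CPM. Mitochondrially encoded transcripts had a median of -0.36 (camera adjusted p = 0.401), with mt-Cytb at 1592 ± 62.4 against 2057 ± 394 CPM and mt-Co1 at 1580 ± 270 against 1767 ± 307 CPM. Red cell and platelet markers had a median of 6.45 (camera adjusted p = 0.0725, 0.00242 without KLRG1-positive library 3 and 0.0107 without both libraries numbered 3). Their haemoglobin genes were high in KLRG1-positive library 2 alone, at 1995 CPM of Hba-a1 and 983 CPM of Hbb-bs, against at most 29.6 and 7.12 CPM in the other 5 libraries. In these last 5 lists, apart from the mast cell list, 0 members passed when adjusted over the list alone.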

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

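Leaving out both libraries of a number, and DESeq2 with the replicate block, were chosen after seeing the data; the other alternatives were planned. No gene among the 203 called changed sign in any setting where it was tested. The numbers of genes higher and lower in KLRG1-positive cells (19 and 184) came to 18 and 180 with DESeq2 size factors, 14 and 177 with upper-quartile factors, 13 and 186 with library size only, and were 19 and 184 with a minimum absolute log2 fold change of 1. They were 37 and 282 without the filter (26868 genes tested), 48 and 351 with the stricter filter (14067 tested), and 346 and 1377 with DESeq2; DESeq2 called all 203 genes but also called 62 genes in simulated data without change. Limma-voom gave 0 and 3 (804 and 1738 at an unadjusted p under 0.05), the replicate block 0 and 53, and DESeq2 with the replicate block 609 and 1697. Leaving out libraries gave 0 to 5 genes higher and 0 to 168 lower, with fewer samples in each fit; for the other changes the cause was not tested.

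The 10 lists past camera's threshold became 0 with an estimated correlation and 3 with fry, 13 without the filter, 11 with the replicate block, and 9 to 12 without libraries. The log2 fold change of Klrg1 lay between 3.54 and 5.30 when libraries were left out; it passed with DESeq2 (4.05, adjusted p = 1.42e-05) and with DESeq2 and the replicate block (4.67, adjusted p = 2.89e-13), while its adjusted p without libraries ran from 0.0646 to 0.448 and it passed in no other fit.

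Over the other named genes, 888 values under alternatives kept their direction and side of the threshold, 267 lost the call, 37 gained it and 32 changed sign. All sign changes were in genes that had not passed. By setting, Fos was 0.00287 without the filter, 0.33 with limma-voom, 0.35 with the replicate block and 0.36 with DESeq2 and the block; Dusp1 was -0.0758, -0.0244 and -0.0266 and H2-Ab1 0.12, 0.11 and 0.11 under the last 3 of these. Over the fits with libraries left out, values ran from -0.43 to 0.74 for Junb, -0.47 to 0.15 for Ets1, -0.53 to 0.29 for Cd96, -0.65 to 0.47 for Fos, -0.0702 to 1.55 for Dusp1, -1.28 to 0.25 for Cd74, -0.63 to 0.91 for H2-Ab1, -0.99 to 8.45 for Hbb-bs and -0.287 to 0.0756 for mt-Co1. The cause was not tested. With the replicate block, 25 of the 27 named genes that had passed no longer did (Lum and Col6a5 still did), Tbx21 passed, the ILC3 list was lost and the effector regulator and inhibitory receptor lists were gained. Over all list members, named or not, 11 lost the call and 10 gained it, among them Tbx21, Il23r, Cd3e, Cd3d, Themis, Trac, Cd79a, Ms4a1 and Ebf1. The block changed no other call of a list or list member. With 17323004 to 23946073 counts per library, depth limits mainly the genes at or near 0 in KLRG1-positive cells, and the fold changes of those without a count there are bounds.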

Other observations

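The test of other splits of the libraries was set before its result was seen; those of fibroblast genes and of mesenchymal transcription factors were set before the values of their genes were seen, but on lists chosen after matrix genes had been seen among the lower genes. Those of free RNA, of a lower ILC2 share, of T cells, of B cells, of depth and of a shared animal or day were chosen only after the result was seen, as were the other marker lists of this section and the collagen count. 2 further tests were also run, and were dropped from the weighing after their results were seen, to keep it to 3 explanations a pattern. The test of adventitial rather than alveolar fibroblasts, chosen after the calls, came out against that explanation, because 63.6% of alveolar markers reached 10 CPM in KLRG1-negative cells; these markers were also judged unspecific only after this. The test of plasma cells as a further source, set beforehand, did not decide: Jchain was at least 398 CPM in every KLRG1-negative library and highest there in the library with the highest ratio of Ighm to Ms4a1, but not so among the KLRG1-positive libraries.

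Collagen genes were more frequent among the genes lower in KLRG1-positive cells than among the other tested genes. Of 25 tested collagen alpha chain genes, 11 were among the 184 lower genes and 24 had negative log2 fold changes (odds ratio 67.9, Fisher's exact test over genes, two-sided, p = 2.33e-15; genes are not independent replicates). The family was chosen after collagen genes had been seen among the lower genes, so this p describes the pattern and gives no independent support. All 3 KLRG1-negative libraries lay above all 3 KLRG1-positive ones for 10 of 12 adventitial fibroblast markers, 5 of 11 alveolar fibroblast markers, 3 of 8 smooth muscle and pericyte markers and 7 of 7 mesothelial markers, against 15.2% of all tested genes and 5% by chance in this direction. The adventitial marker Pi16 averaged 264 CPM in KLRG1-negative and 3.04 CPM in KLRG1-positive cells (adjusted p = 0.0384, and 0.0876 with the block, in which it did not pass), and the mesothelial marker Upk3b 254 and 2.00 CPM (adjusted p = 0.0588). The alveolar marker Npnt went the other way, at 40.8 and 146 CPM (adjusted p = 0.0916). Ccl11, which encodes eotaxin 1, averaged 71.2 and 0.0711 CPM (adjusted p = 0.0196, and 0.0549 with the block, in which it did not pass), and Il33 averaged 90.7 and 1.18 CPM without passing (adjusted p = 0.115). Of these markers Dpp4, Ly6c1, Npnt and Scn7a also exceeded 10 CPM on average in KLRG1-positive cells, and Tcf21 is on both the alveolar and the transcription factor list.

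Matrix transcripts were abundant in the KLRG1-negative libraries and near 0 in the KLRG1-positive ones. Free RNA from lysed stromal cells present alike in both sorts needs similar levels, which the pattern itself lacks. The median ratio of the KLRG1-positive to the KLRG1-negative mean over 16 fibroblast genes was 0.00777. These genes were chosen after matrix genes were seen among the lower genes, so the ratio describes the pattern and is no independent test. Free RNA that differed between the sorts was not tested. Fibroblasts sorted among the KLRG1-negative cells may be a source: 93.8% of the 16 genes, 6 of which were among the 184 lower genes, reached 10 CPM and lay above every KLRG1-positive library, with Serping1 at 451 CPM and Col6a2 at 356 CPM the most abundant, and Pdgfrb, at 10.2, 43.5 and 21.1 CPM against 20.8, 5.77 and 13.0 CPM, the exception. Fibroblasts carry no haematopoietic lineage markers and many display CD90, so the stated gate would not remove them by itself, although the stated purity was above 90%. ILCs transcribing matrix genes without other mesenchymal genes need such genes to be absent. The bounds set beforehand did not decide, because 58.3% of 12 mesenchymal transcription factors reached 1 CPM above every KLRG1-positive library, between the bounds. The levels argue against this explanation only for the genes they cover, not for the pattern as a whole. The median factor stood at 3.11 CPM in KLRG1-negative and 0 CPM in KLRG1-positive cells, although only 1 factor reached 10 CPM. Over 12 adventitial fibroblast markers, 10 of them above every KLRG1-positive library, the medians were 87.9 and 0.443 CPM. That list was chosen after the result was seen and holds matrix genes such as Col14a1 and Mfap5. The 11 alveolar fibroblast markers differed less, with medians of 12.6 and 1.26 CPM and 5 of them above every KLRG1-positive library. ILCs that express such genes as well, or another difference between the 2 ILC populations themselves, were not tested. Mesothelial cells as a source were not tested either. All 7 mesothelial markers lay above every KLRG1-positive library, with medians of 104 CPM in KLRG1-negative and 1.28 CPM in KLRG1-positive cells.

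T and B cell markers were higher as sets in the KLRG1-negative libraries by camera with the preset correlation. Neither set passed with an estimated correlation (adjusted p = 0.364 for each) or by fry (adjusted p = 0.0734 and 0.107). A lower ILC2 share that raises every other cell type alike is argued against by the fixed lists, whose median log2 fold changes were -3.37 for T cell, -3.42 for B cell and -0.53 for macrophage markers. The macrophage list may not measure macrophages alone, with Cd74 at 1591 and H2-Ab1 at 641 CPM in KLRG1-positive cells. A shared rise of T and B cells only stays open, since their medians were alike. A lower ILC2 share with unequal gains of the other cell types was not tested and stays open too. The 16 fibroblast genes had a median of -6.97, which differed from the macrophage list by 6.44 (permutation over genes, p = 1e-04, the smallest that 10000 permutations can give). They were chosen after matrix genes were seen among the lower genes, so this gap and its p add no independent support. B cells as the only source of immunoglobulin transcripts are argued against too, since the ratio of Ighm to the B cell gene Ms4a1 ran from 11.4 to 260 among the 6 libraries, a 22.8-fold range; Jchain, a plasma cell gene, stood at 1625, 398 and 1273 CPM in the KLRG1-negative and 265, 198 and 520 CPM in the KLRG1-positive libraries. T cells sorted among the KLRG1-negative cells may contribute: 7 genes of the T cell receptor complex and co-receptors, led by Cd8b1 at 650 CPM, deviated together within groups, with a median over 21 gene pairs of r = 0.912 and rho = 0.886 in 6 libraries (permutation p = 1e-04 for both, the smallest possible with 10000 draws) and r = 0.669 without the first library of each group, the farthest from the median. A lineage gate commonly removes T and B cells, all 7 genes are also on the fixed T cell list, and 5 of them exceeded 10 CPM on average in KLRG1-positive cells. Since deviations were also shared by library number, genes that vary together in any cell could correlate likewise. The correlations and their permutation p therefore do not show which cells held these transcripts. The 7 were chosen after the result was seen, and the other receptor complex genes on that list were mixed. Trdc (56.9 against 5.41 CPM, KLRG1-negative against KLRG1-positive) and Tcrg-C2 (39.5 against 5.62) went the same way. Cd3g (456 against 237), Trbc2 (953 against 668) and Trbc1 (405 against 353) differed less. Tcrg-C1 (40.4 against 48.1) and Tcrg-C4 (114 against 376) went the other way.

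Same-numbered libraries of both populations deviated together. In the libraries numbered 1 the 16 immediate early genes lay below those numbered 2 and 3, by a median log2 difference of -2.47 in KLRG1-negative and -1.87 in KLRG1-positive cells. Lower depth of the libraries numbered 1 is argued against for these 16 genes. With all libraries thinned to 17323000 counts, and so at equal depth, the median differences stayed at -2.47 in KLRG1-negative and -1.80 in KLRG1-positive cells. For other genes depth was not tested. A shared animal or handling day for each number may explain that all 6 libraries correlated best with their own number, but it cannot be told apart from other causes, because the labels do not say what a number stands for. No biological explanation was tested.

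The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 19 genes higher and 184 lower, and the highest count in 1 direction among the other splits was 30, with KLRG1-negative libraries 1 and 3 and KLRG1-positive library 1 on 1 side; 2 of the 10 splits reached 19 and 1 reached 184. For the lists the real split gave 10 and the highest other 8, so 1 of the 10 reached 10. Of the 4 splits that part all 3 same-numbered pairs, the 3 others called 0 genes by edgeR quasi-likelihood, with 74 to 164 genes at an unadjusted p under 0.05 against 2389 for the real split, and up to 7 lists.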
